A study of Mus musculus with 3 samples.

How the data were processed

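RNA was isolated with the RNeasy mini kit and labelled with the 3DNA Array 900 kit, per the labels' protocols. Wild-type RNA carried Cy3 and mutant RNA Cy5 on replicates 1 and 3, and the dyes were exchanged on replicate 2, per the labels. The deposited values were taken as log2 ratios of both channels of each array, on the evidence of the values: they lie on both sides of 0, and steps between frequent values match log2 of small whole-number ratios. Centring by the authors was inferred from array medians of 0.009, 0 and 0.001, which are also each array's most frequent value. How it was done is not given in the sources used here, nor are the scanner, background correction, normalization within arrays or spot filter. Scale and centring were thus read from the values, and the numerator of the ratio remains unstated. No value was blank. No array intensities were used here, so no filter on dim spots was possible.

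Many spots shared 1 value per array, 0.009, 0 and 0.001. These were 4547, 6470 and 8518 probes (11.7%, 16.6% and 21.9%), and 13039 probes were at it on at least 1 array. Olfactory receptor genes made up 7.15%, 5.77% and 5.22% of them against 2.39% of all probes. These spots were read as having both channels at the lowest signal, which the values do not prove. A ratio of 0 at such a spot is then no measurement.

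Of 38880 probes, 30457 had 1 gene symbol in the platform annotation, 0 had several and 8423 had none. The 21476 symbols were set against RefSeq names of assembly GRCm38.p6, used for names only: 12795 were current, 8317 were updated through a synonym and 364 were kept as given. Probes of a symbol were averaged, and probes without one stayed as features of their own. Positions are not printed because the array's genome build is not given in the sources used here.

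Replicates 1 and 2 were averaged to 1 biological pair and tested with replicate 3 as the other pair, in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05). The study's description names 2 samples per genotype, with no statement on litters or pooling, so that p-values concern these pairs alone. Total degrees of freedom were 2.08. Values after ± are limma's moderated SE, which draws each feature's spread towards a value common to all features. They are not the plain SE between the pairs, and limma's p-values rest on them too. Features at least 1.5-fold from 1 on each array in the same direction were counted, and counted again with 1 array's sign turned. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

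Before the data were examined, 40 gene lists of cell types, chromatin, cell cycle, signalling, stress and metabolism were fixed, naming 1164 different genes, of which 1093 were measured. They were tested with cameraPR on the moderated statistics (preset correlation 0.01, lists of at least 5 genes). Alternatives were camera with an estimated correlation, fry, and 10000 random lists of the same size drawn from features with a symbol. The rule for named genes, also fixed then, took the 12 highest and 12 lowest genes of 1 sign on all arrays, ranked by the array nearest to 0. It also took Smarca1, Smarca5, Cdkn1a and the sex-linked genes, and up to 4 members per list. A further gene of that rule and 1 of the 40 lists are not reported here. Genes named outside it are marked as chosen after their values were seen.

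The procedure was tested on simulated data with known changes. At the real spread 1 unaltered feature was called. At 0.05 of that spread all 67, 67 and 66 features altered by 1, 2 and 4 were recovered, with 4 false calls. Lists of 30 genes shifted by 0.5 were called in 18 of 20 cases, by 1 in 20 of 20, and unshifted in 1 of 20. Members of these simulated lists varied independently, so the shares do not apply to lists with correlation. The errors of all features came from 1 pool and most of the simulated lists were shifted. The shares thus need not hold for real lists without correlation either. The estimated correlation in the real data was 0.75 for the meningeal list and -0.016 for the respiratory chain list. Alternatives covered centring, scaling, single probes, each array left out, a dye term, the arrays as independent or blocked, robust eBayes, single probes without those of Sdha, other thresholds and a filter on extreme and 0 values.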

Results

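Gene expression in the embryonic mouse cortex was measured on 3 two-colour microarrays, each of which set RNA of mice with exon 6 of Snf2l deleted against RNA of wild-type controls. Snf2l is the older name of Smarca1, an ATPase of the ISWI family of chromatin remodellers. Cortices were dissected at E15.5 (embryonic day) from mice of the 129Sv background. RNA came from 2 samples per genotype. Replicates 1 and 2 compared the same pair of RNAs with the dyes exchanged, and replicate 3 compared the other pair, so that n = 2 biological pairs. Each array gave a log2 ratio for 38880 probes, summarised to 28332 features, of which 19909 carried a gene symbol. The array medians were 0.009, 0 and 0.001 and the SDs were 1.253, 1.315 and 1.263. The number of arrays limits the precision, and spot brightness was not used here.

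The question set by the design was which genes differ between mutant and wild-type cortex. Positive values are read here as higher in the mutant, a direction that is likely but not stated: the labels place wild type in the first channel and mutant in the second on each array, and the study names mutant versus control. If the ratios were formed the other way round, every sign below would turn. By the labels replicate 3 has the dyes and channels of replicate 1, so that its ratio runs the same way as that of replicate 1 whichever channel was the numerator. The difference between the dye-swapped arrays, which holds the dye effect, correlated with replicate 3 at r = 0.071 over all features and 0.137 over the genes of the lists fixed in advance. That is the sign the labels predict, but weak, and an exchange of the 2 genotypes in pair 2 would not show in it.

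The targeted gene, Smarca1, was represented by 1 probe, whose position relative to the deleted exon is not given in the sources used here, so that it checks neither the labels nor the deletion. Its log2 ratios were -0.017 and 0.36 on the arrays of pair 1 and 3.11 on pair 2. The mean was 1.64 ± 1.04 (limma's moderated SE, n = 2 pairs), with limma's adjusted p = 0.852. Smarca5, the related ISWI ATPase Snf2h, read 0.33, 0.29 and 0.62 on replicates 1 to 3, with a mean of 0.46 ± 0.24 (moderated SE). Its 2 probes differed in sign on replicates 1 and 3. Cdkn1a, an inhibitor of cell cycle progression, read -1.74, -0.58 and 0.18. Its 2 probes differed in sign on replicate 3, at 0.97 and -0.62.

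Of 28332 features, 0 passed limma's moderated test of mutant against wild type at an adjusted p of 0.05, and the lowest adjusted p was 0.852. At an unadjusted p of 0.05 there were 715 features, 287 higher and 428 lower in the mutant, where chance alone gives 1417. A one-sample t statistic over the 3 arrays gave 0 features too after adjustment. In simulated data with the spread of these arrays, 0 of 67 features altered by 1 on the log2 scale were recovered, 0 of 67 altered by 2 and 44 of 66 altered by 4. Differences of 1 or 2 on the log2 scale were thus not detectable with 2 pairs. The simulation drew the errors of all features from 1 pool, so its recovery of changes of 4 need not hold here. Hoxa5, at a mean of -4.58, had limma's adjusted p = 0.852.

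The genes lowest on every array were led by Hoxa5, a homeobox gene of posterior body patterning, at -4.27, -4.85 and -4.60 on replicates 1 to 3. Its mean was -4.58 ± 0.22 (moderated SE, n = 2 pairs, limma's adjusted p = 0.852). Adamtsl4, a gene of the extracellular matrix, followed with -4.96, -3.94 and -3.87, and Saa4, a serum amyloid, with -4.31, -3.09 and -3.17. Genes of signalling in this group were Itpr3, an inositol trisphosphate receptor, and Irak2, an interleukin receptor kinase. Their means were -3.92 ± 0.61 and -3.61 ± 0.77 (moderated SE). Ptgds, a prostaglandin D synthase made in the leptomeninges, had a mean of -3.92 ± 1.06 and S100a9, a protein of neutrophils, one of -3.10 ± 0.26. Cacng1, a calcium channel subunit of skeletal muscle, averaged -3.31 ± 0.70, and Tmod1, which caps actin filaments, -2.46 ± 0.27. Stbd1, the connexin gene Gja5 and Tecta averaged -3.13, -2.33 and -2.47. None of these 12 passed the test, the adjusted p being 0.852 for each.

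The genes highest on every array were led by Klkb1, plasma prekallikrein, at 3.65, 2.91 and 2.40. Its mean was 2.84 ± 0.37 (moderated SE, n = 2 pairs, limma's adjusted p = 0.852). Celf5, an RNA-binding protein of neurons, averaged 2.38 ± 0.49, and Rhbg, an ammonium transporter, 3.42 ± 0.80. Zfp706 averaged 1.98 ± 0.30 and Il1f5, an antagonist of interleukin signalling, 2.20 ± 0.45. The olfactory receptors Olfr862 and Olfr248 averaged 2.17 and 3.79. The other 5 were gene models or family members of unassigned function: 4930442E04Rik at 4.40, Gm11346 at 4.20, E230013L22Rik at 2.29, 1100001I12Rik at 2.15 and Fam47c at 2.04. The adjusted p was 0.852 for each of these 12 as well. Among the 12 highest and 12 lowest genes, 5 had 1 or 2 values at a whole-number ratio to their array's most frequent value. These may be dim spots, which could not be filtered out here.

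**Figure D1:**
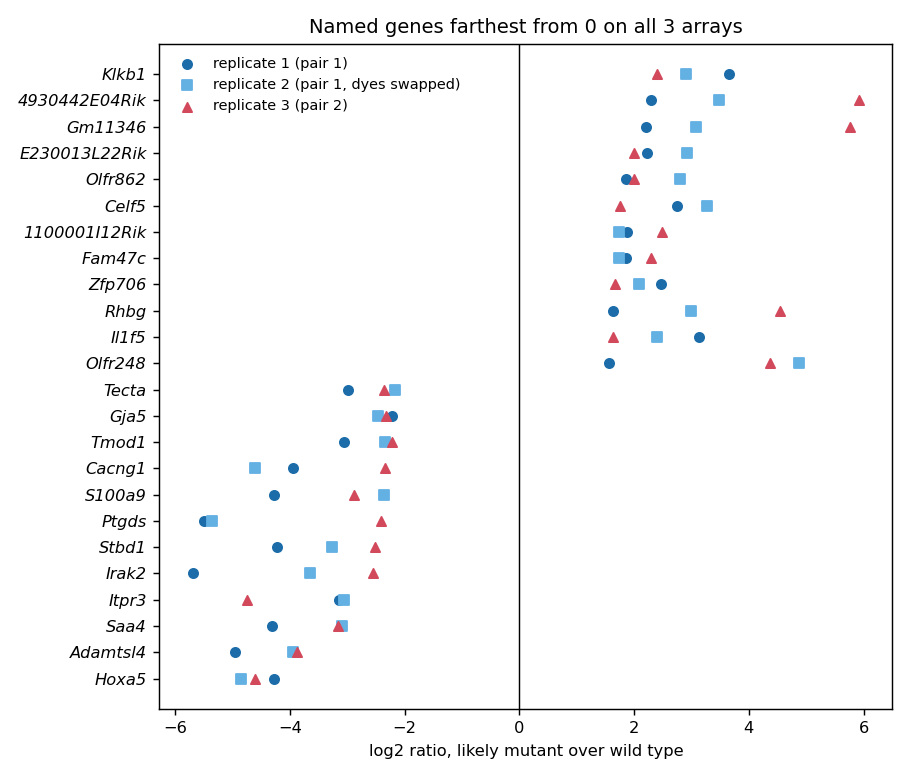
Log2 ratios (horizontal axis) of the 12 highest and 12 lowest genes by their least extreme array (vertical axis), with a point for each of the 3 arrays. Hoxa5 lies between -4.85 and -4.27 on the 3 arrays, and none of the 24 genes passed the adjusted test.

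Features at least 1.5-fold from 1 in the same direction on all 3 arrays numbered 808, of which 317 were higher and 491 lower. That count was 1146 with the sign of replicate 3 turned, so the pairs shared fewer large ratios in one direction than in opposite directions. It was 570 with replicate 2 turned and 348 with replicate 1 turned. Of 4169 features past 1.5-fold the same way on replicates 1 and 2, 1954 were past it on replicate 3, and 41.4% of those pointed the same way. Across features, which are not independent replicates, Pearson's r was 0.245 between the dye-swapped arrays and -0.066 between the mean of pair 1 and pair 2. Spearman's rho was 0.208 and -0.054. Over the 1093 genes of the lists fixed in advance, r was 0.752 between the dye-swapped arrays and -0.287 between the pairs. These values were 0.845 and -0.354 over the 258 genes on lists of other cell types, and 0.531 and -0.138 over the remaining 835. Among list genes, pair 1 thus gave repeatable ratios that pair 2 did not share, most of all for markers of other cell types. Pair 2 was measured on 1 array without a dye swap, so its own repeatability is unknown. Of probes 3 to 5 (log2) from the most frequent value, 19.9% were at a whole-number ratio to it on replicate 3. That share was 9.0% and 11.5% on replicates 1 and 2, and 2.2% by chance.

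Markers of cartilage, bone, muscle and skin had the medians farthest from 0 of the 40 lists in pair 1, and lay on the other side of 0 in pair 2. The list's median was -4.64 on replicate 1 and -4.46 on replicate 2, and 31 of 35 genes were below 0 on both. On replicate 3 the median was 0.63, and of 31 genes with a measured value 23 were above 0. Both pair 1 medians lay below all 10000 random lists of that size and the replicate 3 median above all of them. Chosen after the values were seen, the myosin light chain gene Myl1 read -9.72, -9.41 and 0.66, and Myog, a regulator of muscle differentiation, -6.86, -8.63 and 1.586. The keratin gene Krt15 read -2.40, -5.22 and 6.62. The genes of 1 sign on all arrays included Col9a1, a cartilage collagen (-3.87, -4.13 and -1.44), and Myh8, a myosin of developing muscle (-2.551, -2.004 and -1.028). Over the pairs the list missed the threshold in the preset-correlation test (adjusted p = 0.0876). With an estimated correlation, a test of little power with 2 pairs, adjusted p = 0.9903.

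Other cell types outside the neuronal lineage had medians below 0 in pair 1 too. Meningeal and fibroblast genes had medians of -2.30, -2.56 and 0.59, with 28 of 31 below 0 on both pair 1 arrays and 23 of the 30 measured on replicate 3 above 0. Among them, chosen after the values were seen, the collagen gene Col1a1 read -4.50, -3.50 and 2.82, and Lum, a matrix proteoglycan, -4.88, -5.02 and 3.89. Choroid plexus genes had medians of -0.98, -1.38 and 0.08, endothelial and pericyte genes -0.76, -1.08 and 0.42, and red cell genes -1.17, -0.67 and 0.024. Microglial and leukocyte genes had medians of -0.90, -0.67 and -0.074, and Lyz2, the lysozyme of macrophages, read -2.06, -1.06 and -1.39. Markers of later glia had medians of -0.71, -1.04 and 0.001 but were mixed, with 10 of 19 genes below 0 and 5 above 0 on both pair 1 arrays. Aldh1l1, of astrocytes, read 0.025, 0.50 and 0.22 and the glutamate transporter gene Slc1a2 0.23, 0.28 and 0.54. The adjusted p was 0.0876 for the choroid plexus and microglial lists, 0.180 for the meningeal list and 0.366 or more for the other 3. With an estimated correlation adjusted p = 0.9903 for all 6.

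**Figure D2:**
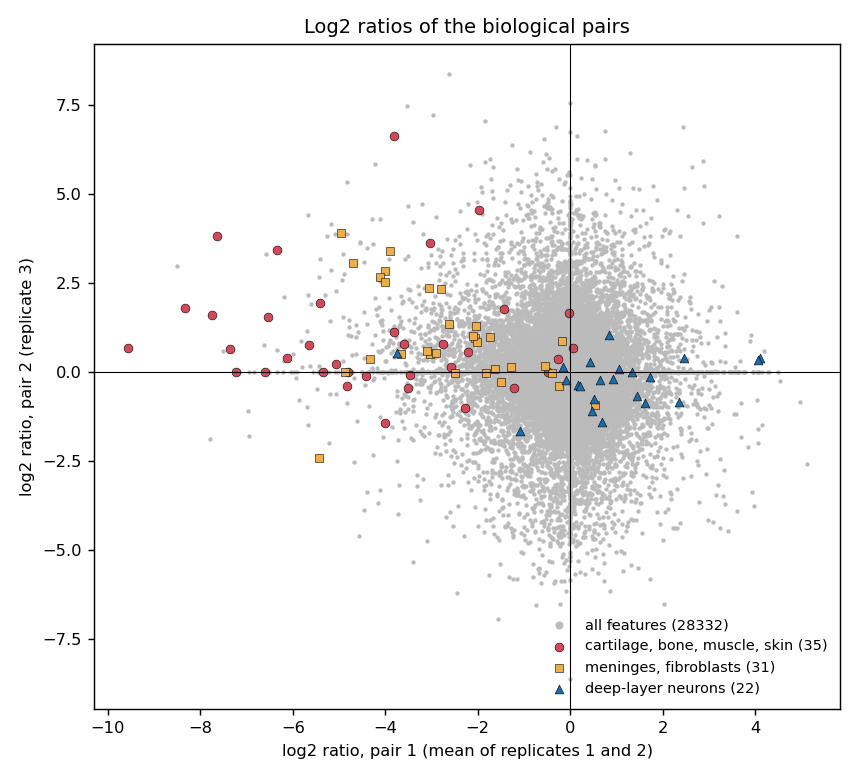
Log2 ratio of each of 28332 features in pair 1 (horizontal axis, mean of replicates 1 and 2) and in pair 2 (vertical axis, replicate 3), with 3 marker lists in colour. Genes of cartilage, bone, muscle and skin spread to the left in pair 1, with a median of -4.00 on this axis, and mostly lie above 0 in pair 2.

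Most lists of neuronal markers had medians above 0 in pair 1, beside these medians below 0, though not every member went with its list. Deep-layer neuron genes had medians of 0.72, 0.92 and -0.21, with 17 of 22 above 0 on both pair 1 arrays. Tbr1, a transcription factor of layer VI and young projection neurons, read 3.90, 4.23 and 0.33, Fezf2, which specifies subcerebral projection neurons, 4.53, 3.70 and 0.39, and Bcl11b 2.60, 2.32 and 0.39. Ccn2, of the same list and chosen after its values were seen, read -3.57, -3.94 and 0.51. Intermediate progenitor genes had medians of 0.59, 0.68 and -0.087, with 13 of 18 above 0 on both pair 1 arrays. Insm1, a factor of basal progenitor formation, read 2.08, 2.25 and 0.28. Interneuron and ventral genes had medians of 0.45, 0.52 and 0.019. Their adjusted p was 0.0876, as for intermediate progenitors, and 0.398 for deep layers. Upper-layer genes had medians of 0.24, 0.32 and 0.001, young neuron genes 0.26, 0.38 and -0.12, and apical progenitor genes 0.037, 0.031 and -0.13. In the young neuron list, 3 of the genes named by rule were below 0 on all arrays: the neurofilament genes Nefl (-1.89, -0.57 and -0.22) and Nefm (-0.87, -0.80 and -1.46), and Cntn2 (-1.26, -0.44 and -0.34). Cajal-Retzius genes had medians of 0.30, 0.37 and -0.58, hem and hippocampal genes 0.34, -0.055 and -0.10, and thalamic and midbrain genes -0.14, -0.13 and -0.038. None of these passed, and adjusted p was 0.9903 or more with an estimated correlation.

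**Figure D3:**
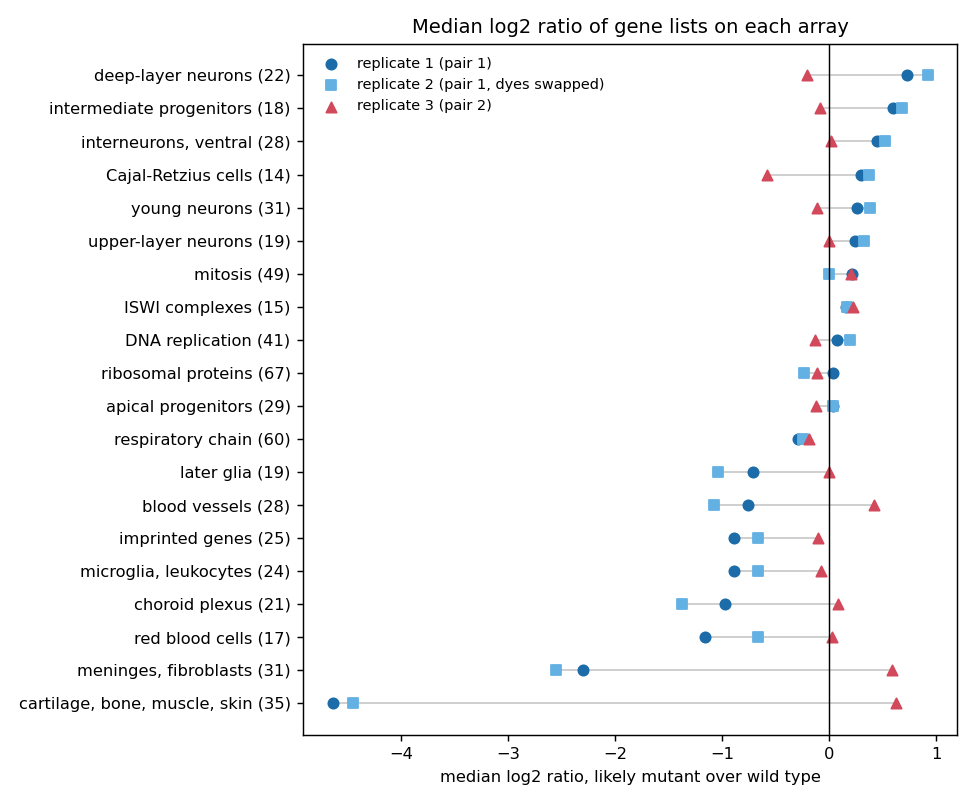
Median log2 ratio (horizontal axis) of 20 of the 40 gene lists (vertical axis, with the number of genes measured) on each array. The lists of cartilage, bone, muscle and skin, meninges, choroid plexus, blood vessels, red cells, microglia and later glia lie at -0.67 or lower on both arrays of pair 1 and between -0.074 and 0.63 on replicate 3.

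Of all 40 lists, 0 passed an adjusted p of 0.05 and 9 had an unadjusted p under it. The rotation test fry called 0 at either. Against random lists of the same size, which take no account of correlation between the genes of a list, 7 passed, namely the list of cartilage, bone, muscle and skin and those of meninges, red cells, deep layers, interneurons, mitosis and imprinted genes. Respiratory chain and choroid plexus genes were among those that passed when the 3 arrays counted as separate evidence, and with an estimated correlation 0 lists passed there, the lowest adjusted p being 0.655. No list member passed when adjusted over the list alone, the lowest such p being 0.232, nor over all genes.

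Genes of the respiratory chain had medians of -0.29, -0.24 and -0.19 over 60 genes. Of these, 18 were below 0 on all 3 arrays, 2 were above and 40 were mixed. Ndufa4 read -0.57, -0.63 and -0.91, and Ndufa1 -0.98, -0.31 and -0.88. The list's adjusted p was 0.0876 in the preset-correlation test, and adjusted p = 0.9903 in camera with an estimated correlation. That correlation was -0.016, below the preset 0.01, so correlation between members does not account for the rise. The test with an estimated correlation has little power with 2 pairs, whichever the list. With every probe as a feature its median over the pairs moved from -0.24 to -0.092 (adjusted p = 0.516). Sdha, chosen after its values were seen, made up 78 of those 159 probes, and without it the median was -0.288 (adjusted p = 0.0459, and adjusted p = 0.958 with an estimated correlation). Ribosomal protein genes had medians of 0.039, -0.23 and -0.12, glycolytic and hypoxia genes -0.38, -0.49 and -0.059, and cholesterol synthesis genes 0.089, -0.25 and 0.30. Imprinted genes had medians of -0.89, -0.67 and -0.11 (adjusted p = 0.0876, and adjusted p = 0.9903 with an estimated correlation, here -0.027). Among them Peg3, a paternally expressed zinc finger gene, read -1.23, -1.33 and -1.35.

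Genes of ISWI complexes had medians of 0.15, 0.16 and 0.22, with Rsf1 at 0.29, 0.42 and 0.38. Genes of other remodellers had medians of 0.30, 0.19 and -0.004 and histone genes 0.14, 0.37 and 0.12. Mitotic genes had medians of 0.22, 0 and 0.20, and Cdca3 read 1.18, 0.30 and 1.38. The mitotic list had adjusted p = 0.0876, and adjusted p = 0.9903 with an estimated correlation (-0.017), a test of little power with 2 pairs. DNA replication genes had medians of 0.070, 0.20 and -0.13, cell cycle exit genes -0.19, -0.074 and -0.10, and genes of G1 cyclins and growth -0.19, 0.025 and 0.043. In the last of these, Ccnd1, a cyclin of G1, read -1.25, -0.96 and -0.70 and Mycn 1.02, 1.69 and 0.74.

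Signalling and stress lists did not pass either. Medians were 0.11, -0.092 and 0.018 for Notch, -0.20, -0.045 and 0.052 for Wnt and -0.46, -0.27 and -0.033 for Shh, Fgf and Bmp. Axon guidance genes had medians of 0.26, 0.25 and -0.027, with Slit3 at -1.67, -2.52 and -2.28, and synaptic genes 0.10, 0.24 and -0.088. Immediate early genes had medians of -0.37, -0.40 and 0.46, heat shock and ER stress genes -0.23, -0.27 and -0.29, p53 and apoptosis genes 0.15, -0.033 and 0.003, and interferon response genes -0.87, -0.32 and 0.001. Housekeeping genes had medians of -0.14, -0.28 and 0.37. A few list medians equal their array's most frequent value, 0 on replicate 2 or 0.001 on replicate 3, and are no measurement. Without spots at that value they were 0.15 for mitotic genes on replicate 2, and on replicate 3 -0.069 for upper layers, 0.041 for later glia, 0.63 for the interferon response and -0.50 for the sex-linked list.

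The sex-linked list had medians of 0.31, 0.040 and 0.001 over 8 genes. Eif2s3y, on the Y chromosome, read -1.19, -1.15 and -0.74 and Uty, also Y-linked, -0.92, -0.61 and -0.50, while Xist, the RNA of the inactive X, read 3.18, 1.28 and 0.41. The 2 probes of Uty and those of Xist differed in sign on at least 1 array. Kdm5d read 0.43, -0.50 and 0.58, Usp9y 0.20, 0.25 and -0.97, Zfy1 1.12, -0.17 and 0.001, Zfy2 0.66, 0.79 and 0.001, and Tsix -1.94, 1.54 and 0.001. The 0.001 of Zfy1, Zfy2 and Tsix is the most frequent value of replicate 3 and no measurement, which leaves these genes without a value in pair 2. Adjusted p-values were 0.852 or more.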

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

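The alternatives without spots at the most frequent value, without markers of other tissues, without probes of Sdha and with an estimated correlation in the fits to separate arrays were chosen after seeing the data. The count of 0 genes at adjusted p 0.05 held under every alternative in which genes were tested, limma with a dye term, independent arrays and the one-sample t statistic included; unadjusted p 0.01 gave 44. The count of 808 features became 1218 with every probe as a feature, 272 at 2-fold, 1781 at the laxer of the fold thresholds tried, and 2175 to 4169 with 1 array left out, where fewer arrays had to meet the threshold. The correlation between the pairs was -0.094 to -0.0091 with 1 array of pair 1 left out, -0.105 without spots at the most frequent value and -0.287 over list genes. Between replicates 1 and 2 it was 0.350 without those spots, 0.219 without tissue markers and 0.752 over list genes. The number of lists called, 0 in the test fixed in advance, was 13 with 3 arrays as independent replicates, 13 with the pair as a random block, 6 with a dye term fitted to the 3 separate arrays, 7 against random lists, 5 with every probe as a feature but none of Sdha, and 1 without spots at the most frequent value. The fits with 13 calls had the same lists: the joint list of cartilage, bone, muscle and skin, and meninges, choroid plexus, red cells, microglia, intermediate progenitors, deep layers, interneurons, other remodellers, mitosis, glycolysis, respiratory chain and imprinted genes. The 6 were the joint list, meninges, choroid plexus, interneurons, respiratory chain and imprinted genes. With an estimated correlation 0 lists passed with 3 arrays as independent replicates (lowest adjusted p = 0.655) and 0 with a dye term (0.861). Both fits left few degrees of freedom, so this test had little power there too. For the random block it was not run. The 5 were the joint list, deep layers, interneurons, respiratory chain and imprinted genes, at adjusted p = 0.0459 each, and 0.958 with an estimated correlation in that setting. The 1 was the joint list (adjusted p = 0.00125), and adjusted p = 0.971 with an estimated correlation in that setting. The adjusted p of the respiratory chain list lay between 0.00237 and 0.516 over the alternatives tested with the preset correlation. Over the pairs it was 0.9903 in camera with an estimated correlation and 0.9825 in fry. The fits with 13 and 6 calls count the dye-swapped arrays as separate evidence, and the block correlation of 0.245 came from replicates 1 and 2 because limma's own estimate could not be had from 3 arrays. With replicate 1, 2 or 3 left out, 0 lists passed where a test remained. Of 40 lists, 15 had a median that changed sign under at least 1 alternative, that without Sdha not counted. Tsix, at -0.10, turned to 0.77 without replicate 1 and 0.29 with a dye term (-0.97 without replicate 2). Zfy1, at 0.24, turned to -0.083 without replicate 1 (0.56 without replicate 2). Replicates 1 and 2 differed in sign for both genes, at -1.94 and 1.54 for Tsix and 1.12 and -0.17 for Zfy1. Both genes have no measured value on replicate 3, so leaving out replicate 1 or 2 sets the sign. Without replicate 3 there is 1 pair and no gene test. Alternatives for missing values were not run, since no value was blank. Signal over background is unknown here. The test fixed in advance is itself paired, since each ratio sets 1 mutant RNA against 1 wild-type RNA.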

Other observations

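All tests of explanations in this part were chosen after the pattern had been seen. The bounds for 3 of them were written before the deciding value was computed: the 3 head tissue lists read jointly, the saturated spots, and the share of features as far from 0 as Eif2s3y. The resampling of genes for the saturated spots and the separate readings by array were added after the medians were known. The remaining tests were written after their values were known, among them the separate readings of muscle, cartilage and epidermis.

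The genes named in this paragraph and the next were chosen after their values were seen, apart from Polr2a. Of 17 genes spotted many times, 8 had medians below 0 on both arrays of pair 1 and above the most frequent value on replicate 3, with no test run. B2m, a light chain of MHC class I, had medians of -1.59, -1.70 and 0.73 over 77 spots, with SDs of 0.768, 0.991 and 0.856. Gsn, the actin-severing protein gelsolin, had medians of -2.87, -2.99 and 1.41 over 24 spots. Hprt, often taken as a reference gene, had medians of -0.59, -0.60 and 0.58 over 77 spots, whereas Ywhaz, also spotted 77 times, had 0.17, 0.010 and 0.31, Polr2a (35 spots) 0.42, 0.33 and 0.28, and Actb (32 spots) 0.085, -0.62 and -0.13.

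Later lists of tissues near or far from the cortex were written after the pattern had been seen, leaving out genes of the first muscle and meningeal lists, and 0, 0 and 1 of the muscle, cartilage and epidermis genes were on a list fixed in advance. Skeletal muscle had medians of -2.55, -2.28 and 0.001 on replicates 1 to 3, with 28 of 36 genes below 0 on both pair 1 arrays. Cartilage and bone had -3.03, -2.11 and 0.001, with 16 of 23 below 0. Epidermis had -0.94, -0.27 and 2.01, the last above all 10000 random lists. Liver had -0.40, 0 and 0.043, and gut, lung and kidney -0.23, 0 and 0.001. Several of these medians are the most frequent value of their array and no measurement. Without spots at that value, medians were -2.74, -2.48 and 0.15 for muscle, -3.27, -2.88 and 0.15 for cartilage and bone, -0.94, -0.36 and 3.36 for epidermis, -0.74, 0.065 and 0.56 for liver and -0.37, -0.22 and 0.32 for gut, lung and kidney. Actn2 read -5.20 and -6.78 in pair 1, Tnnt2 -4.28 and -5.54 and Col9a2 -2.96 and -3.70, but Ttn, the largest muscle protein, read -0.76 and -2.29, and Neb 3.53 and -2.95. How many of these genes the cortex itself expresses is not known from ratios.

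Markers of head tissues lay far below 0 in pair 1 only, whereas epidermis departed most of the later lists in pair 2, where its median was 2.01, and as a hypothesis 1 RNA of pair 1, the wild-type one if the direction is as read, may have held muscle and cartilage, and 1 of pair 2, then the mutant one, skin, of which the part on pair 2 was not tested. The prediction that later lists of muscle, cartilage and epidermis would all lie below -1 on both arrays failed, since the highest of their medians was -0.273, for epidermis on replicate 2, which also argues against epidermis alone; muscle alone is argued against by the later cartilage and bone list (higher median -2.11, with upper bounds of -1.34 and -0.52 from resampled genes), and cartilage and bone alone by the later muscle list (-2.28, with -2.06 and -1.45). Dye bias is argued against by the 88.6% of members with 1 sign on both dye orientations, and an effect of the deletion common to both pairs by the median of 0.63 on replicate 3, if the genotypes there are as labelled. Muscle together with cartilage and bone stays open and undecided: the separate readings were made once the joint prediction had failed, and the liver list, meant to stay above -0.5, lay at -0.74 on replicate 1 over measured spots. A biological difference between the animals of the pairs and an exchange of the genotypes in pair 2 were not tested and stay open too. Replicate 3 is the only array of pair 2, so noise and dye bias could not be measured there.

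The median of the respiratory chain genes lay below 0 on each array, with 18 of 60 genes below 0 on all 3. Saturated spots held at a shared value are argued against as the whole source on replicate 1, where that value was 0.085 and so above 0, and on replicate 2, where it was -0.615 but the median without the 8 of 159 probes near either value was -0.187 over 55 genes, with an upper bound of -0.070 from resampled genes. The bound written in advance for all 3 arrays decides nothing, since leaving out spots held above 0 cannot raise a median. A shared value was not searched for on replicate 3, where the 142 spots near both values of the other arrays had an SD of 0.345. Muscle in pair 1 is argued against as the whole source by replicate 3, where the list lay at percentile 1.12 of random lists. Those random lists were not matched for brightness. The upper bound on replicate 3 from resampling the same 55 genes was -0.046, below 0 but close to it. The list did not pass its test, so an effect of the genotype stays a hypothesis, and differences in RNA quality or cell composition were not tested. Leaving out spots near a shared value does not reach spots saturated in 1 channel or an offset that varies with brightness. Neither of these was tested.

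Xist was above 0 and Eif2s3y and Uty below 0 on all arrays, taking the mean of each gene's probes. The sex of the embryos cannot be told apart from noise, since the median of the Y-linked genes was 0.31 and -0.42 on replicates 1 and 2 (6 genes measured) and -0.62 on replicate 3 (4 genes measured), and the probes of Xist differ. Of features with a symbol, 1.91% lay as far from 0 on their least extreme array as Eif2s3y, which was predicted in advance to argue against chance if under 5%. That bound was wrong for this pattern, as it concerns 1 gene of either sign picked from 8 listed ones (the chance that at least 1 of 8 lies as far is 14.3%), and the pattern is of 3 genes with a direction. Of 10000 random draws of 7 features, 5.83% had at least 3 in the directions of 1 sex on all arrays, either way round, a share close to the bound of 5%, so chance may account for the pattern and is not excluded.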
